A study of Mus musculus with 6 samples.

How the data were processed

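Skin of mouse embryos at embryonic day 17.5 was profiled by bulk RNA-seq, with 3 libraries of Tie1 knockout skin and 3 of control skin on the C57BL/6N strain background. Per the labels' protocols, frozen skin was extracted with Trizol, mRNA was purified with oligo(dT) beads, fragmented, converted to cDNA and amplified by PCR. The sample titles of both groups carry the letters ECD beside Tie1, which the labels do not explain and which were not interpreted here. The labels do not state in words which part of Tie1 was deleted or in which cells, whether the libraries of a group came from separate embryos or litters, or which part of the body the skin was taken from. The p-values below that come from tests between samples therefore measure only the spread between these samples.

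Each deposited file holds, per the file headers, 1 estimated count (an expected read count) per gene, keyed by NCBI gene number and symbol. The deposited values were not normalized: library totals differed, from 19826856 to 20591164 reads, and 31.0 to 31.9% of the 19131 genes of a library had a value more than 0.001 away from a whole number. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and the genome build GRCm38.p6, with no role or order given for any of them. Estimated counts of this kind share reads between genes with similar sequence by a model, so members of near-identical families such as the alpha globins are uncertain one by one. Whether counting used the strand is not given in the sources used here, so reads of genes that overlap cannot be told apart. The gene numbers of 19001 genes (99.32%) matched a GRCm38.p6 gene table, from which all coordinates are taken (1-based), and 98.7% of the matched genes were protein coding. The tables are therefore mostly protein-coding genes, and long noncoding RNAs were not analysed here. Of the 19131 genes, 517 had no read in any library, and 17205 to 17341 had a read in a given library.

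Groups and replicate numbers were taken from the labels. Estimated counts were rounded to whole numbers, genes with low counts were removed with filterByExpr at its minimum count of 10, and TMM factors were computed, leaving 15035 genes. The groups were compared with the robust quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) with genotype as the only term and Benjamini-Hochberg adjustment over all genes tested. A gene is called changed at an adjusted p under 0.05. The standard error of a log2 fold change was taken as its absolute value divided by the square root of the F statistic. Levels are TMM-scaled CPM, given as mean ± SD of 3 libraries. Because 1 read is worth about the same in every library, a count of 3 reads corresponded to 0.146 to 0.151 CPM, and this was taken as the floor. For genes with few reads the ratio of summed reads is given with its exact (Clopper-Pearson) 95% interval, which covers counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules.

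Before the data were examined, 31 gene lists holding 417 genes (textbook markers of vessels, of the other cells a skin sample can hold, and of stress and growth programs) were fixed, with no gene in more than 1 list and Tie1 in none. Of these genes 415 matched the files and 390 were tested, and 30 lists had the minimum of 3 tested members. Lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, on voom log2 values, with Benjamini-Hochberg adjustment over the 30 lists, and again with an estimated correlation and with fry. At the preset correlation camera compares the genes of a list with all other genes, so its p counts genes rather than samples. In addition, the mean log2 CPM (prior count 2) of 5 endothelial lists was taken relative to the pan-endothelial list in each library and compared by a two-sided exact permutation test, whose smallest possible p for 3 against 3 libraries is 0.1. The rule for named genes, also fixed beforehand, took Tie1, every tested member of the venous and angiopoietin-TIE lists, up to 4 members with the smallest p of every other list, and from the table of all genes up to 12 higher and 12 lower genes with the largest fold change among called genes with a mean of at least 1 CPM in either group and no overlap between the groups. It passed over predicted genes and Y-linked genes, and gave 12 higher and 11 lower genes.

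Alternatives fixed beforehand were RLE and upper-quartile scaling, no filter and a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit that was not robust, the replicate number as a block, a score of embryo sex, a skeletal muscle score, abundant genes left out, a prior count of 0.5, and leaving out each library. The sex score used 4 Y-linked genes, because Xist, planned as part of it, was not analysed here. Fits without knockout 1 and control 1, with a hair follicle score and with a score of 8 posterior Hox genes were chosen after seeing the data. The count test was tested on simulated data with the same 15035 genes and 6 libraries and 200 genes changed: at a fold of 1.5 it recovered 27.5% with 7 false calls, at a fold of 2 it recovered 74.0% with 9, and at a fold of 4 it recovered 92.0% with 20, so the share of false calls can exceed 5%. With the venous list lowered and the tip cell list raised 1.5-fold, camera recovered both and called none of the others. The genes were drawn independently there, so this does not show how often camera calls lists whose genes move together. A scan of neighbouring genes, written after the data were seen, ranked a simulated 1.5-fold raised window first of 14828 windows. Because the chromosome 11 run was found by its values, it was compared with the largest run of 2 to 10 neighbours anywhere in the genome in 2000 random orders of the tested genes, a test also chosen after the data were seen. Tables were handled with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.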

Results

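TIE1 is an orphan receptor tyrosine kinase of endothelial cells that acts together with the angiopoietin receptor TIE2, and the series asks how its loss alters vessel sprouting and the assembly of veins. Whole skin of E17.5 mouse embryos was sequenced from 3 Tie1 knockout and 3 control samples, so that each value mixes vessels with epidermis, dermis, muscle and blood. The 6 libraries held 19826856 to 20591164 estimated reads. No pair of libraries was a duplicate, since the counts of any 2 libraries differed by 9.95 to 51.3 times the sampling variance. These differences did not follow genotype alone. Knockout 3 differed from control 3 by 11.1 times that variance and from knockout 1 by 47.18 times. The closest pair, at 9.95, was control 2 and control 3. Y-linked transcripts were present in knockout 2, knockout 3 and control 3 and near background in the other 3 libraries, so both groups contained embryos of both sexes.

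Tie1 itself (gene 21846, chromosome 4, 118471191 to 118489849, GRCm38.p6) stood at 3.07 ± 1.11 CPM in knockout and 56.4 ± 5.02 CPM in control skin (SD, n = 3 each). Its log2 fold change was −4.20 (SE 0.23, edgeR adjusted p = 0.00387). The knockout libraries held 84, 53 and 46 estimated Tie1 reads and the control libraries 1187, 1023 and 1215, which put the knockout at 5.41% of the control level (95% counting interval 4.64 to 6.28%). All 3 knockout libraries thus matched their labels. Because the files give 1 value per gene, these reads cannot be placed on exons inside or outside the deleted part.

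Loss of Tie1 was accompanied by a called change in 24 genes of embryonic skin, and vascular genes were prominent among them. That count does not show how many genes changed, since the test recovered 27.5% of simulated 1.5-fold changes. Esm1, the secreted proteoglycan endocan made by sprouting endothelial tip cells, rose 25.2-fold, from 0.708 ± 0.151 to 18.0 ± 2.68 CPM. Apln, the tip cell ligand apelin, rose from 21.4 ± 2.18 to 60.0 ± 6.88 CPM, and Notch4 and Angpt2 rose from 13.4 ± 0.672 to 28.0 ± 2.64 CPM and from 18.8 ± 2.64 to 35.8 ± 0.901 CPM. In the opposite direction, Selp, which encodes the leukocyte adhesion receptor P-selectin of venules, fell from 3.36 ± 0.518 to 0.132 ± 0.0745 CPM, below the floor, and Vwf, the von Willebrand factor gene, fell from 35.4 ± 3.13 to 15.3 ± 2.11 CPM (SD, n = 3 for all).

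Of 15035 genes tested by edgeR's quasi-likelihood test, 24 changed at an adjusted p under 0.05, 13 higher and 11 lower in the knockout. An unadjusted p under 0.05 was reached by 1116 genes, a number that alone does not mark genotype. Setting knockout 1, knockout 2 and control 1 against the other libraries gave 1375 such genes, with 0 called. All 24 were separated, with every library of one group above every library of the other. Over all genes 2076 (13.8%) were separated, against 10% by chance. Apart from Tie1, 9 of the 23 called genes belonged to the 10 vascular lists, which hold 123 of the 15034 other genes tested, where 0.188 would fall by chance (odds ratio 83.7, 95% interval 31.3 to 214, Fisher's exact p = 9.06e-14). This p and interval treat genes as independent. The genes were measured in the same 6 libraries and can move together, so neither value measures the spread between samples. The number of calls depended on which libraries were used. It was 11, 1 and 8 without knockout 1, 2 and 3, and 8, 3 and 3 without control 1, 2 and 3, in fits with fewer samples. Without both knockout 1 and control 1 it was 139, including all 24. With DESeq2 it was 207, including all 24, and with limma-voom 15, all among the 24.

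**Figure D1:**
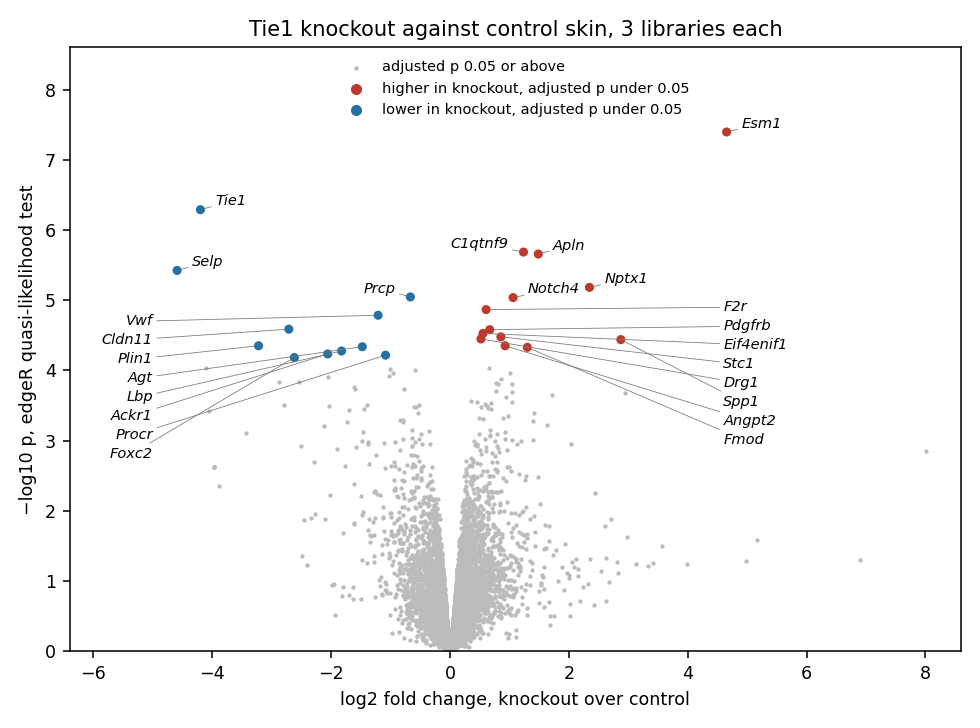
Log2 fold change of knockout over control (horizontal axis) against −log10 of the unadjusted edgeR p (vertical axis) for 15035 genes, 3 libraries per group. The 24 genes with an adjusted p under 0.05 are coloured and named, with Esm1 at 4.65 and Selp at −4.59.

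Genes of venous endothelium were lower in the knockout. Of the 13 tested venous genes 3 fell, 7 were lower when adjusted over the list alone, and none was higher by either count (camera adjusted p = 6.60e-10; adjusted p = 0.102 with an estimated correlation). The median log2 fold change was −0.31 and the mean −1.27. Selp had a log2 fold change of −4.59 (SE 0.38, edgeR adjusted p = 0.0113). It had 8 knockout reads against 204 control reads, a ratio of 25.2-fold (95% counting interval 12.5 to 59.1). Vwf fell by 1.21 (SE 0.12, edgeR adjusted p = 0.0247). Ackr1, a chemokine-binding receptor of venular endothelium, fell by 2.06 on the log2 scale (SE 0.25, edgeR adjusted p = 0.0396). The gene of E-selectin, Sele, lies next to Selp on chromosome 1 and had 5 knockout against 90 control reads, a log2 fold change of −4.06 that did not pass the test (SE 0.66, edgeR adjusted p = 0.0875) and ranged from −5.56 (without knockout 3) to −3.52 with 1 library left out. Aplnr, the receptor of apelin, stood at −1.60 (SE 0.21, adjusted p = 0.0678) and Lrg1 at −2.79 (SE 0.44, adjusted p = 0.0847; −3.42 without knockout 3), neither past the edgeR threshold. Slco2a1, a prostaglandin transporter, had a log2 fold change of −0.31 (SE 0.083, edgeR adjusted p = 0.364). Nr2f2, which encodes the transcription factor COUP-TFII, had a log2 fold change of −0.0051 (SE 0.080) and Ephb4 of −0.18 (SE 0.085). Neither passed the edgeR threshold (adjusted p = 0.995 and 0.689). Whether these 2 genes differ from the other venous genes was not tested. Whole skin also does not show which cells a transcript came from, so their levels do not settle the state of venous endothelium. Nrp2 stood at −0.17 (SE 0.14), and the adhesion and cytokine receptor genes Vcam1, Il1r1 and Icam1 at 0.35 (SE 0.33), 0.11 (SE 0.089) and 0.0011 (SE 0.15), none past the edgeR threshold (adjusted p = 0.845, 0.821 and 0.999).

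Tip cell and sprouting genes were higher. Of 15 tested, 2 rose, 8 were higher when adjusted over the list alone, and none was lower by either count (camera adjusted p = 2.74e-11; adjusted p = 0.131 with an estimated correlation). Esm1 had a log2 fold change of 4.65 (SE 0.20, edgeR adjusted p = 0.000605) and Apln of 1.49 (SE 0.11, edgeR adjusted p = 0.00827). Pgf, which encodes placental growth factor, stood at 1.01 (SE 0.14) and Trp53i11 at 0.69 (SE 0.11), with edgeR adjusted p = 0.0547 and 0.0869. The 24 pan-endothelial genes, which include Pecam1 and Cdh5, moved both ways. Their median log2 fold change was 0.017, their mean −0.036 and the camera direction down (adjusted p = 0.508; adjusted p = 0.862 with an estimated correlation). None was called by edgeR and 9 had an unadjusted p under 0.05 (5 higher, 4 lower). DESeq2 called 3, all lower, and limma-voom none, and 4 were higher and 3 lower when adjusted over the list alone. Plvap, the diaphragm protein of fenestrated capillaries, stood at −0.59 (SE 0.077, edgeR adjusted p = 0.0528), Emcn at −0.52 (SE 0.097), and Robo4, a receptor of the stable endothelium, at 0.40 (SE 0.096).

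**Figure D2:**
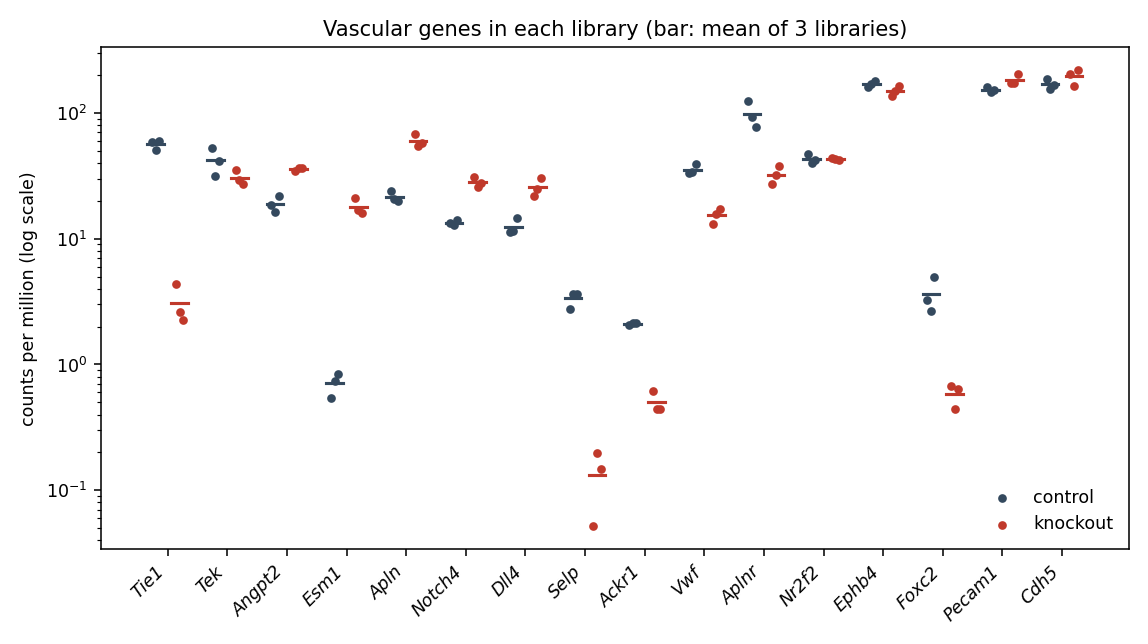
CPM of 16 vascular genes in each library, on a log axis, with points for the 3 control (dark) and 3 knockout (red) libraries and a bar at the mean. Esm1 lies near 0.708 CPM in control and 18.0 CPM in knockout skin, while Nr2f2 and Ephb4 overlap between the groups.

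Set against the pan-endothelial list within each library, the venous list stood at −1.84 ± 0.082 in the knockout and −0.73 ± 0.10 in the control (mean log2 CPM difference, SD, n = 3 each), a difference of −1.11 with exact permutation p = 0.1, the smallest that 3 against 3 allows. The tip cell list differed by 0.85 and the lymphatic list by −0.44, both also at exact permutation p = 0.1. The arterial list differed by 0.14 (exact permutation p = 0.2) and the angiopoietin-TIE list by 0.013 (exact permutation p = 0.7). Adjusted over these 5 comparisons the values were 0.167, 0.167, 0.167, 0.25 and 0.7, so none could pass 0.05 in this design.

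In the angiopoietin-TIE list, Angpt2, a TIE2 ligand released by endothelial cells, was the 1 of 8 tested genes that rose (log2 fold change 0.93, SE 0.11, edgeR adjusted p = 0.0353). Adjusted over the list alone, 2 were higher and 2 lower, and the list as a whole was not called (camera adjusted p = 0.415; adjusted p = 0.839 with an estimated correlation). Tek, the gene of TIE2, had a log2 fold change of −0.46 (SE 0.20) and Angpt1, the agonist ligand, of −0.53 (SE 0.23), with edgeR adjusted p = 0.676 and 0.671. Svep1, an extracellular matrix protein, stood at 0.96 (SE 0.18), and the endothelial nitric oxide synthase gene Nos3 and the flow-responsive factor gene Klf2 at −0.63 (SE 0.11) and −0.43 (SE 0.14), with edgeR adjusted p = 0.168, 0.135 and 0.533. Ptprb and Foxo1 were at −0.014 (SE 0.096) and −0.085 (SE 0.12).

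Among Notch pathway genes, Notch4, an endothelial Notch receptor, rose (log2 fold change 1.06, SE 0.098, edgeR adjusted p = 0.0173). It was the 1 of 11 tested that passed, over all genes and adjusted over the list alone, and the list was not called (camera adjusted p = 0.122; adjusted p = 0.658 with an estimated correlation). The arterial list of 13 genes was not called either (camera adjusted p = 0.334; adjusted p = 0.718 with an estimated correlation), with 2 genes higher and 1 lower when adjusted over the list alone. Dll4, the Notch ligand of arteries and tip cells, stood at 1.05 (SE 0.15, edgeR adjusted p = 0.0702) and the arterial connexin gene Gja5 at −0.49 (SE 0.11, edgeR adjusted p = 0.238). In the BMP and ALK1 list the median of 10 genes was 0.016, the mean −0.086 and the camera direction down (adjusted p = 0.415; adjusted p = 0.839 with an estimated correlation). The Notch list was called higher without control 3 (0.00754) and with the posterior Hox score (0.000523), and without control 2 the BMP and ALK1 list lower (0.0411).

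Of 11 lymphatic genes 1 fell, Foxc2, a transcription factor of lymphatic and venous valves, from 3.62 ± 1.18 to 0.585 ± 0.121 CPM (log2 fold change −2.62, SE 0.32, edgeR adjusted p = 0.0411). Adjusted over the list alone, 5 were lower and 2 higher, and the list was lower by camera (adjusted p = 0.0409; adjusted p = 0.658 with an estimated correlation). Stab2, a hyaluronan receptor, and Klhl4 went opposite ways without passing, at 1.72 (SE 0.26) and −1.45 (SE 0.23), with edgeR adjusted p = 0.0743 and 0.0869. The lymphatic call was lost without knockout 1, knockout 2, control 1 or control 3, at camera adjusted p = 0.0602, 0.160, 0.343 and 0.0957, within a range of 0.00114 to 0.658 over all 17 settings.

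Pdgfrb, the receptor that mural cells use to respond to endothelial PDGF-B, rose from 99.5 ± 7.20 to 158 ± 6.01 CPM (log2 fold change 0.67, SE 0.072, edgeR adjusted p = 0.0330), the 1 of 12 mural cell genes that passed. Adjusted over the list alone, 4 mural genes were higher and 3 lower. Higd1b, a pericyte marker, stood at 1.40 (SE 0.24) and the smooth muscle genes Cnn1 and Myh11 at −1.37 (SE 0.27) and −0.82 (SE 0.20), none past the edgeR threshold. The list was not called (camera adjusted p = 0.102; adjusted p = 0.434 with an estimated correlation), but was called higher without control 1 (0.0242) and without knockout 1 and control 1 (0.0318).

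Genes of the hypoxia response were higher together. Of 17 tested, 16 had a positive log2 fold change, with a median of 0.47, and 11 were separated (13.8% over all genes, 10% by chance). When adjusted over the list alone 11 were higher (camera adjusted p = 1.50e-13; adjusted p = 0.266 with an estimated correlation). None passed edgeR over all genes, 13 had an unadjusted p under 0.05, all higher, and DESeq2 called 8 and limma-voom 0. Pgk1, a glycolytic enzyme, stood at 585 ± 42.7 CPM in knockout and 406 ± 24.2 CPM in control (log2 fold change 0.53, SE 0.083, edgeR adjusted p = 0.0847), and Pdk1 at 0.49 (SE 0.082) and Ndrg1 at 0.80 (SE 0.15), with edgeR adjusted p = 0.103 and 0.165. The VEGF ligand list of 6 genes, whose member Vegfa is itself induced by low oxygen, was higher by camera (adjusted p = 0.00144; adjusted p = 0.354 with an estimated correlation). In that list 4 genes were higher when adjusted over the list alone, among them Vegfc at 0.67 (SE 0.12) and Vegfa at 0.41 (SE 0.14). None passed edgeR over all genes, 4 had an unadjusted p under 0.05, and DESeq2 called 1 and limma-voom 0.

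The adipocyte list was lower by camera. Plin1, which coats lipid droplets, fell from 7.37 ± 2.36 to 0.786 ± 0.295 CPM (log2 fold change −3.22, SE 0.37, edgeR adjusted p = 0.0353), the 1 of 11 adipocyte genes that passed, and 5 were lower when adjusted over the list alone (camera adjusted p = 0.000611; adjusted p = 0.358 with an estimated correlation). The median log2 fold change was −0.48 and the mean −0.95, with 7 genes below 0 and 4 above. Those above 0, named after their values were seen, were Dgat2 at 0.55, the brown fat genes Ucp1 and Cidea at 0.44 and 0.15, and Lipe at 0.054. None passed the edgeR threshold, and each fell below 0 with 1 library left out: Dgat2, Ucp1 and Lipe without knockout 1 (−0.042, −0.0022 and −0.032) and Cidea without control 2 (−0.036). Adipoq, the adiponectin gene, had 24, 7 and 10 knockout reads and 404, 59 and 157 control reads (log2 fold change −3.88, SE 0.88, edgeR adjusted p = 0.308; −4.58 without knockout 1 and −2.95 without control 1). Pparg, the transcription factor of fat cell differentiation, stood at −0.65 (SE 0.13, edgeR adjusted p = 0.156). Mast cell genes were lower by camera as well (adjusted p = 4.57e-09; adjusted p = 0.131 with an estimated correlation). All 9 had a negative log2 fold change, with a median of −0.55, and 5 were lower when adjusted over the list alone. None passed edgeR over all genes, 6 had an unadjusted p under 0.05, and DESeq2 called 4 and limma-voom 0. The mast cell protease genes Cma1 and Cpa3 stood at 455 ± 14.0 against 775 ± 116 CPM and at 615 ± 43.6 against 1066 ± 193 CPM in knockout and control (SD, n = 3), with edgeR adjusted p = 0.0678 and 0.109.

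Skin composition differed between libraries in ways that only in part followed genotype. The hair follicle score, the mean log2 CPM of that list, was 1.96, 3.90 and 4.33 in the knockout and 2.46, 3.98 and 4.75 in the control libraries, so that knockout 1 and control 1 stood apart from the rest. Without these 2 libraries 139 genes were called, including all 24. Posterior Hox genes, which mark position along the body, were chosen after their values were seen. Hoxc10 stood at 12.5, 17.0 and 18.7 CPM in the knockout libraries, 16.4 CPM in control 1, and 6.09 and 1.23 CPM in control 2 and control 3. The mean log2 CPM of 8 such genes was 2.94, 3.25 and 3.21 against 3.04, 2.26 and 1.74, which moves in part with the venous, tip cell, adipocyte and mast cell groups. With that score as a covariate 5 genes were called, of which 3 were among the 24, while the venous and tip cell lists stayed called by camera (adjusted p = 3.04e-07 and 2.09e-08, within ranges over all 17 settings of 3.40e-10 to 0.102 and 4.95e-13 to 0.131). Hemoglobin transcripts took 1.61% of the reads in control 1 and 0.663 to 0.857% in the other 5 libraries.

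**Figure D3:**
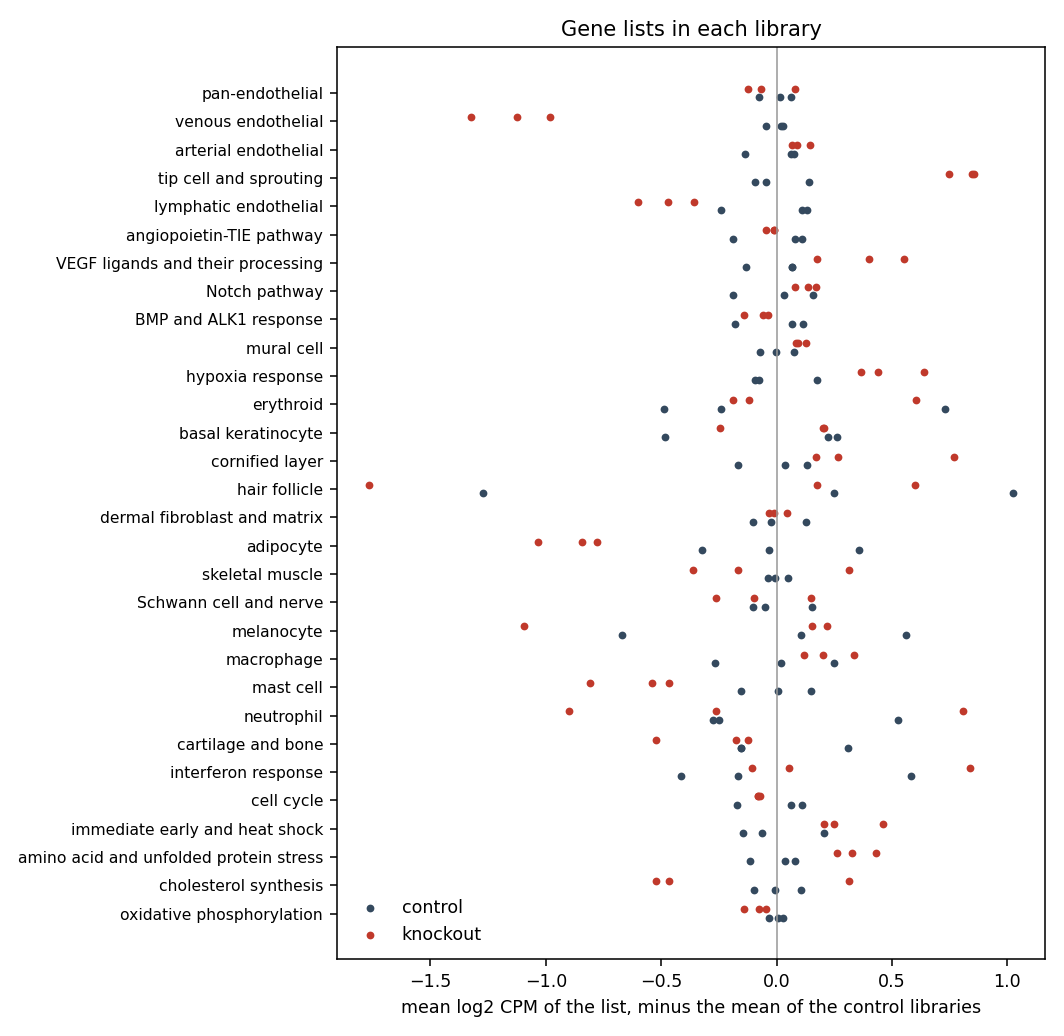
Mean log2 CPM of each of the 30 tested gene lists in each library, minus the mean of the 3 control libraries (dark, control; red, knockout). The venous list is lower and the tip cell list higher in all 3 knockout libraries, while the hair follicle list is lowest in knockout 1 and control 1.

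The remaining 18 lists covered other cells and general programs. Of their 230 tested genes none passed edgeR, 18 had an unadjusted p under 0.05 (12 higher, 6 lower), DESeq2 called 3 and limma-voom 0. Macrophage genes were higher by camera (adjusted p = 0.00683; adjusted p = 0.658 with an estimated correlation), with Cd68, a lysosomal glycoprotein, at 0.66 (SE 0.19, edgeR adjusted p = 0.430). The macrophage call was lost without knockout 1 (0.0818), without control 2 (0.372) and with the posterior Hox score (0.633), and held in 12 of 17 settings. Immediate early and heat shock genes were higher (camera adjusted p = 8.48e-05; adjusted p = 0.414 with an estimated correlation), with 3 of 14, Fos, Junb and Dusp1, higher when adjusted over the list alone. Amino acid and unfolded protein stress genes were higher (camera adjusted p = 0.00115; adjusted p = 0.358 with an estimated correlation), as were interferon response genes (camera adjusted p = 0.0498; adjusted p = 0.839 with an estimated correlation). The interferon call held in 9 of 17 settings and was lost without knockout 2 (0.863, direction down), control 1 (0.172) or control 2 (0.730), and with the sex (0.956, direction down) or muscle score (0.0799). Oxidative phosphorylation and cell cycle genes were lower (camera adjusted p = 0.00101 and 0.00144; adjusted p = 0.434 and 0.658 with an estimated correlation), by medians of −0.079 and −0.11, and the cell cycle call was lost without control 1 (0.185) and with the sex score (0.0515). Without knockout 1 and control 1, the calls of the immediate early, amino acid stress, oxidative phosphorylation and cell cycle lists were lost (0.0979, 0.0979, 0.220 and 0.264). Cholesterol synthesis genes were lower (camera adjusted p = 0.00519; adjusted p = 0.658 with an estimated correlation), and Idi1 was the 1 of 12 lower when adjusted over the list alone. Knockout 1, at a mean log2 CPM of 6.09, lay above every control library (5.68 to 5.88) in that list, and knockout 2 and knockout 3 lay below, at 5.31 and 5.26. The cholesterol call was lost without knockout 2 (0.160), knockout 3 (0.252) or control 2 (0.0636) and with the posterior Hox score (0.276) or the sex score (0.316), and held in 10 of 17 settings.

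The lists of the main tissues of skin were not called. Camera gave an adjusted p = 0.648 for basal keratinocyte, 0.0769 for cornified layer, 0.314 for hair follicle, 0.544 for dermal fibroblast and matrix, 0.170 for skeletal muscle, 0.281 for melanocyte and 0.286 for cartilage and bone genes. It gave an adjusted p = 0.544 for erythroid, 0.835 for Schwann cell and nerve and 0.544 for neutrophil genes. With 1 library left out, cornified layer genes were called higher (without knockout 2, knockout 3 or control 2, adjusted p = 0.0222, 0.0257 and 0.00858), hair follicle genes lower (without knockout 3 or control 1, 0.0323 and 0.000120; also without both knockout 1 and control 1, 0.0189), and skeletal muscle, melanocyte and basal keratinocyte genes lower (without knockout 3, 1.09e-07, and without control 1, 0.0111 and 0.0117). With the posterior Hox score, basal keratinocyte genes were called the other way, higher (0.00435), as were cornified layer genes (0.0284), while skeletal muscle and erythroid genes were called lower (0.0221 and 0.0163). Basal keratinocyte and cornified layer genes were also called higher with the hair follicle score (0.0199 and 0.000220). With the sex score cornified layer genes were called higher (0.000601), and hair follicle, skeletal muscle and melanocyte genes lower (4.68e-05, 0.0175 and 0.000162). The erythroid median was −0.28 and its mean 0.096 with a downward test. The Schwann cell median was 0.027 and its mean −0.063 with a downward test. The neutrophil median and mean were 0.14 and 0.10 with a downward test, and the fibroblast median and mean 0.067 and −0.0050 with an upward test. The liver and yolk sac list had 1 tested gene, Alb, at −0.56 (SE 1.01, edgeR adjusted p = 0.924), and was not tested as a list. Over the 30 lists camera called 14, 7 higher and 7 lower. With an estimated correlation it called none, 4 lists had an unadjusted p under 0.05, and fry called 2, the venous (adjusted p = 0.0146) and tip cell (adjusted p = 0.0166) lists.

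Other called genes lay outside the lists. Spp1, the osteopontin gene, and Nptx1, which encodes a secreted pentraxin, rose by 2.87 (SE 0.33) and 2.35 (SE 0.21) on the log2 scale (edgeR adjusted p = 0.0342 and 0.0165). Fmod, a collagen-binding proteoglycan, rose by 1.30 (SE 0.15), the secreted protein gene C1qtnf9 by 1.24 (SE 0.093), Stc1 by 0.86 (SE 0.096) and F2r, a thrombin receptor, by 0.61 (SE 0.060), with edgeR adjusted p = 0.0353, 0.00827, 0.0342 and 0.0228. Genes that fell included Cldn11, a tight junction claudin, at −2.71 (SE 0.29), Lbp, which binds bacterial lipopolysaccharide, at −1.82 (SE 0.22), and Procr, the endothelial protein C receptor, at −1.09 (SE 0.13), with edgeR adjusted p = 0.0330, 0.0379 and 0.0396. The angiotensinogen gene Agt and Prcp, a peptidase that cleaves angiotensin II, fell with log2 fold changes of −1.48 (SE 0.17) and −0.67 (SE 0.062), with edgeR adjusted p = 0.0353 and 0.0173.

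Eif4enif1, which encodes a carrier of the translation factor eIF4E, rose from 88.6 ± 4.73 to 130 ± 1.25 CPM (log2 fold change 0.56, SE 0.061, edgeR adjusted p = 0.0342). Its neighbour Drg1, named after its values were seen, rose by 0.52 (SE 0.059, edgeR adjusted p = 0.0342), and both lie in a run of 5 tested genes from Sfi1 to Pik3ip1 on chromosome 11, 3131850 to 3342971, that were all separated and higher in the knockout. Sfi1, Patz1 and Pik3ip1, also chosen after their values were seen, stood at 0.65 (SE 0.085), 0.45 (SE 0.088) and 0.66 (SE 0.18), with edgeR adjusted p = 0.0528, 0.156 and 0.364. Eif4enif1 and Drg1 were each called in 11 of 20 alternative settings and in 0 of 6 fits with 1 library left out, where they ranged from 0.52 to 0.59 and from 0.49 to 0.54. The annotated ends of Sfi1 and Eif4enif1 overlap, so a few of their reads cannot be assigned to one gene. The next 5 tested genes had a median log2 fold change of 0.061.

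**Figure D4:**
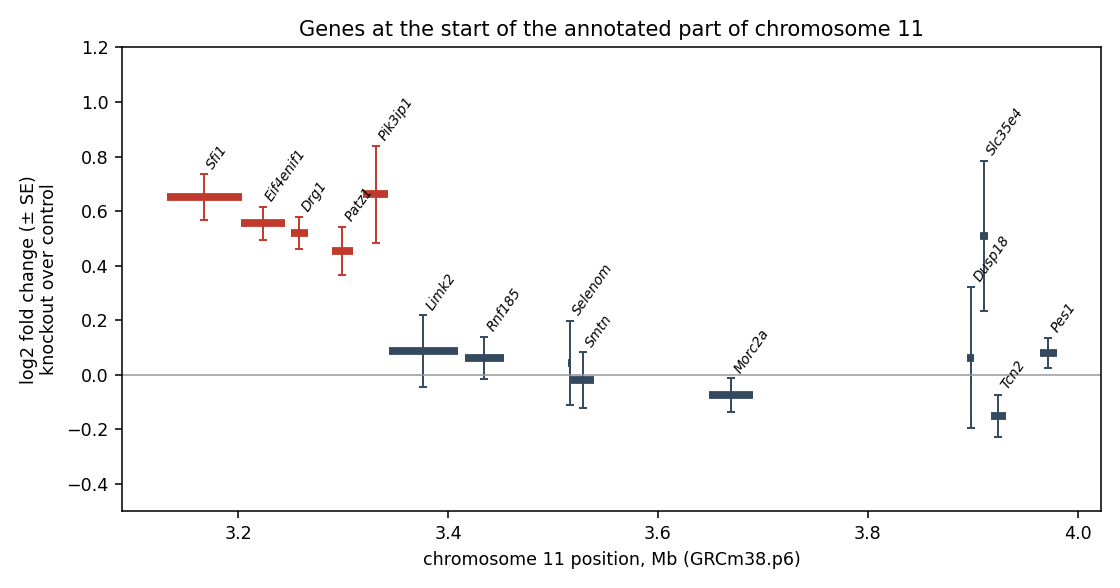
Log2 fold change of knockout over control (vertical axis, bars ± SE) of 14 genes with a mean of at least 10 CPM, drawn over their span on chromosome 11 in Mb (GRCm38.p6). The 5 genes in red lie between 0.45 and 0.66, and Limk2, the next gene, lies at 0.087.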

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

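The fits without knockout 1 and control 1, with a hair follicle score and with a posterior Hox score as covariates were chosen after seeing the data; the other settings were planned. In all 20 alternative settings the 24 called genes kept their sign, and Esm1 passed in all 20, Tie1 in 19 and C1qtnf9 in 18, while Ackr1 and Procr passed in 9. The count of changed genes (higher, lower) was 38 (19, 19) with no filter on low counts, 207 (117, 90) with DESeq2, 15 (11, 4) with limma-voom, 14 (8, 6) with the skeletal muscle score, 139 (70, 69) without knockout 1 and control 1, 114 (67, 47) with the hair follicle score and 5 (2, 3) with the posterior Hox score. The 24 were all called with no filter, DESeq2, the pair left out and the hair follicle score, and 12 with the muscle score, 18 with the sex score and 3 with the Hox score. With the Hox score the standard error grew in 24 of the 24, by a median of 1.42 times, and the log2 fold change moved by a median of 0.078 and at most 0.50. Vwf went from −1.21 (SE 0.12) to −1.14 (SE 0.17) and Angpt2 from 0.93 (SE 0.11) to 1.03 (SE 0.16), while Aplnr, outside the 24, went from −1.60 (SE 0.21) to −2.04 (SE 0.13) and was called (edgeR adjusted p = 0.0167). Leaving out each library in turn gave 1 to 11 changed genes, 1 to 7 higher and 0 to 4 lower, with fewer samples per fit; without knockout 2 the 1 gene was Esm1 and Tie1 stood at −4.10 (edgeR adjusted p = 0.0559), within a range of −4.53 to −4.02. With the replicate number as a block (a paired fit) 52 genes were called, 33 higher and 19 lower, 22 of them shared with the 24. Same-numbered libraries had correlations of 0.411, 0.0431 and 0.266 after group means were removed. Knockout 2 correlated best with control 3 (0.185), while knockout 1 and knockout 3 correlated best with the control of the same number. Whether the numbers pair the samples cannot be told from these values. For lists, camera with an estimated correlation gave adjusted p = 0.102 for venous, 0.131 for tip cell, 0.658 for lymphatic, 0.354 for VEGF ligand, 0.266 for hypoxia, 0.358 for adipocyte and 0.131 for mast cell genes. The estimate for the venous list, 0.0197, lay close to the preset 0.01. With fry the lymphatic, VEGF ligand, hypoxia, adipocyte and mast cell lists had adjusted p = 0.399, 0.144, 0.0751, 0.157 and 0.0508. The lymphatic list was also lost with the replicate block (0.126), without knockout 1 and control 1 (0.614) and with the hair follicle score (0.1001), and it ranged from 0.00114 to 0.343 with 1 library left out, its losing fits from 0.0602 to 0.343. The venous and tip cell lists stayed called in 16 of 17 settings and the hypoxia, adipocyte, mast cell and VEGF ligand lists in 15. The venous list relative to the pan-endothelial list kept its direction in all 9 settings (−1.16 to −1.06 with 1 library left out). Genes that were not called changed sign, most of them near 0 but also Dgat2 (0.55), Ucp1 (0.44), Vcam1 (0.35) and Alb (−0.56), where 1 library was left out. Ptprb became 0.013 with the muscle score, ranged from −0.10 to 0.072 with 1 library left out (above 0 without knockout 1), and became 0.065 without knockout 1 and control 1, and 0.0069 with the hair follicle score. Foxo1 ranged from −0.18 to 0.0047 (above 0 without control 3) and became 0.10 with the Hox score. Nr2f2 became 0.0077 with the sex score, 0.010 without knockout 3, 0.065 without control 1 and 0.054 without knockout 1 and control 1. Vcam1 ranged from −0.094 (without knockout 1) to 0.55. Icam1 became −0.028 with upper-quartile scaling, −0.0062 with no filter, −0.00092 with the block, −0.11 with the sex score, −0.0060 with abundant genes left out, and −0.13, −0.066 and −0.064 without knockout 3, control 1 and control 2, in a range up to 0.13. Ucp1 ranged from −0.0022 (without knockout 1) to 0.69 and became −0.0035 without knockout 1 and control 1. Dgat2 ranged from −0.042 (without knockout 1) to 0.78 and became −0.068 without knockout 1 and control 1. Cidea ranged from −0.036 (without control 2) to 0.28, below 0 also without knockout 3 (−0.024). Lipe became −0.24 with the Hox score and ranged from −0.061 (without control 3) to 0.28, below 0 also without knockout 1 (−0.032) and control 2 (−0.046). Alb ranged from −2.65 to 0.26 (above 0 without control 2). The basal keratinocyte list, not called but higher in direction, turned to lower without control 1 (adjusted p = 0.0117) and was called higher with the posterior Hox score (0.00435) and the hair follicle score (0.0199). The interferon list turned to lower with the sex score (0.956) and without knockout 2 (0.863, in a range from 2.00e-05). The angiopoietin-TIE list relative to the pan-endothelial list turned to −0.036 without knockout 1 and −0.042 without control 2, in a range up to 0.066. With the replicate block the cornified layer list was called higher (0.000830), the hair follicle and melanocyte lists lower (0.000412 and 0.00641), and the interferon call was lost (0.102). Except where stated, the cause was not tested. Depth limits the lowest genes: Selp and Sele in the knockout lie at or below the floor of 3 reads per library in most libraries.

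Of the 10 ways to divide the 6 libraries into groups of 3, the real one called 24 genes and the highest other called 6, and 1 of 10 reached 24; for lists the real one called 14 and the highest other 16, and 2 of 10 reached 14. With 10 divisions no share under 0.05 can be reached. List calls at the preset correlation were common under the other divisions, from 7 to 16. The smallest camera adjusted p there was 0.00920 for the venous, 2.25e-05 for the tip cell and 2.76e-07 for the hypoxia list. The real division gave 6.60e-10, 2.74e-11 and 1.50e-13. For the adipocyte and mast cell lists the smallest was 0.0155 and 0.000148, against 0.000611 and 4.57e-09 for the real one. A camera call at the preset correlation therefore does not by itself mark genotype.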

Other observations

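The tests of coincidence of neighbours, of an extra copy, of embryo sex and of Tie1 loss on chromosome 11, and those of endothelial share and low oxygen, were chosen only after the result was seen, as were the genes of the next paragraph and the hair follicle and Hox scores.

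Of 4 MHC class II genes chosen after their values were seen, and so no test of that pathway, none passed edgeR. Cd74, the invariant chain, stood at 9.07 ± 0.710 CPM in knockout and 17.6 ± 2.29 CPM in control skin (log2 fold change −0.96, SE 0.13, edgeR adjusted p = 0.0547). H2-Aa, an alpha chain, stood at 1.83 ± 0.470 against 5.65 ± 0.731 CPM (log2 fold change −1.62, SE 0.23, edgeR adjusted p = 0.0672), and both were separated in all 6 libraries. H2-Eb1 had a log2 fold change of −1.09 (SE 0.24) and H2-Ab1 of −0.24 (SE 0.18), with edgeR adjusted p = 0.223 and 0.810. Hmox1, which encodes the heme-degrading enzyme heme oxygenase, stood at 261 ± 21.4 against 133 ± 28.7 CPM (log2 fold change 0.97, SE 0.15, edgeR adjusted p = 0.0995; called without control 1, at 1.15, adjusted p = 0.0291).

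Sfi1, Eif4enif1, Drg1, Patz1 and Pik3ip1, neighbours on chromosome 11, were higher by a shared log2 fold change of 0.55 (SE 0.034), with gene folds of 1.37 to 1.58. The errors of the shared value and the chi-square below treat the 5 genes as independent. Taken per library, their mean log2 level differed by 0.57 (SE 0.059), an error that needs no such independence. Coincidence of neighbours is argued against, since 0 of 2000 random orders of the tested genes held, anywhere in the genome, a run of 2 to 10 neighbours as large (summed z over the root of the run length 8.13 against at most 7.23). Embryo sex is argued against as the whole cause, because the shared value stayed at 0.5439 (SE 0.037) with the Y-linked score, although the calls of Eif4enif1 (0.56, SE 0.061, to 0.56, SE 0.069, edgeR adjusted p = 0.0531) and Drg1 (0.52, SE 0.059, to 0.53, SE 0.066, adjusted p = 0.0542) ended as their errors grew. A candidate explanation is 1 extra copy of the segment in the knockout embryos: the 5 folds did not differ beyond error (chi-square 3.24 on 4 degrees of freedom) and their shared value, 0.5478, lies within 2 SE of log2 of 1.5, which is 0.585. An effect of Tie1 loss on these genes cannot be told apart from it, because 3 of 3 knockout libraries lie above every control library and none lacks the gain, and DNA of these embryos was not analysed here.

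The venous list was lower and the tip cell list higher. A lower share of endothelial cells is argued against as the whole cause, since the pan-endothelial mean was −0.03589 (SE 0.063) and the venous mean −1.27 (SE 0.46, with a median of −0.31). With the posterior Hox score as covariate the venous and tip cell means were −1.235 (SE 0.44) and 0.95 (SE 0.35). Adjusting for that score thus did not remove these means. The score is only a proxy for body position of the skin, which is not excluded. These errors are taken over genes, which are not independent. Low oxygen in the tissue may contribute to the tip cell genes, because the hypoxia list was higher in every knockout library (difference 0.4815), but it cannot be told apart from an effect of genotype, with which it moves.

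The adipocyte and mast cell lists had a joint mean log2 fold change of −0.80 (SE 0.25 over 20 genes, which are not independent), with all 9 mast cell genes below 0 but 4 of 11 adipocyte genes above 0 (adipocyte median −0.48, mean −0.95), each of these 4 below 0 in at least 1 fit with a library left out. The mean was −0.8334 with the hair follicle score, −0.8054 with the skeletal muscle score and −0.9912 with the posterior Hox score as covariate, each over 2 SE below 0. These errors are taken over genes and hold no spread between libraries. The hair follicle and muscle scores differed by −0.33 and −0.071 between the groups (knockout minus control), so adding them could move the mean little. The fits with these scores thus could not decide whether what they measure accounts for the mean. Adjusting for the posterior Hox score did not bring the mean nearer to 0. Each score is only a proxy, so hair follicle stage, muscle carried with the skin and body position are not excluded. A lower number of these cells and a lower expression in each cell both remain open, as does an effect of the embryos' general state, which was not tested.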
